A study of Mus musculus with 5 samples.

How the data were processed

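Anti-ACAA2 ChIP-seq was measured in hearts of male C57BL/6J mice in 4 groups: sham or TAC surgery on a diet with 10 or 60 kcal% fat. Each group has 1 library, labelled a pool of 3 hearts. A pooled input sample is also listed; the table analysed here has no column for it, so no background was subtracted. The series title, the design and the antibody label name ACAA2, while the text of the extraction protocol names antibodies against butyrylated and acetylated histone H3 lysine 9. The values were read as anti-ACAA2, as the columns of the table are named.

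The deposited table holds 3885 merged regions. The authors' notes name BWA, SICER and the mm10 build; their versions, the read filters, the fragment extension, the cutoff of the calls and any matching of depth between libraries are not given in the sources used here. The signal deposited for each region and library is the average (and the highest) fragment pileup over the region, per the file headers. The highest values were whole numbers in 100% of regions, so they were not multiplied by a factor for sequencing depth. The log2 ratios deposited by the authors equal the log2 of the ratio of the average signals without a pseudocount (checked here), and 1 to 4 regions per comparison hold text because a signal is 0. The authors also give, for the higher library of a pair, an estimated number of fragments; this number equals the average signal times the region length over a constant, and the same constant was used for the fragments of each library here. A mark for a called interval per library, the total number of called intervals merged into a region (6109 in all), and counts of promoters, CpG islands and genes per region complete the table. The windows behind promoter and gene assignment are not given in the sources used here, and neither is whether the starts count from 0 or 1.

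For each comparison the log2 ratio of the average signal was computed with a pseudocount of 1. Regions at least 2-fold higher and lower were counted, and the median was given with a 95% interval from order statistics (binomial). For the difference between diets, the log2 ratio of TAC over sham on 10% fat diet was subtracted from that on 60% fat diet, and regions were counted beyond 1 log2 unit. The counting interval of a region's ratio is the exact Clopper-Pearson interval of its estimated fragments in the pair, without a pseudocount, so it is wider on the side of a low count than the ratio with the pseudocount would be. Against a signal of 0, a floor of 3 fragments in that library was used. Fragments without molecular identifiers are not independent molecules, so these intervals and the floor cover counting error at most. To gauge counting noise, the fragments of each region in a pair were drawn 100 times from a binomial distribution, and the 2-fold regions were counted. The distribution used each library's share of the pair's fragments over the regions counted. In a subset of regions the draws therefore take up the subset's own shift between the libraries. These draws leave out the effect of the calls: a region enters the table because it was high in at least 1 library. Each comparison was therefore also made in regions called in a library not compared. Shares of regions and genes have Wilson 95% intervals. With 1 library per group there is no SD, no test and no p-value, and no library can be left out in turn.

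The table holds 5134 gene symbols, of which 5014 matched a RefSeq symbol or a single synonym (GRCm38.p6) and 120 did not. Of the 21896 protein-coding symbols 4554 have a region. The gene lists, the named-gene rule, the comparisons and the first set of alternatives were fixed before the data were examined. The 22 lists are those whose results are given, from fatty acid uptake and beta-oxidation to neuron markers; 8 of them are markers of cell types. A list's share is that of its genes with a region, with all protein-coding genes as the background. For the 15 lists with at least 5 genes, the mean log2 ratio over each gene's regions was taken, and the list median was placed among the medians of 10000 random gene sets of the same size, matched in 10 bins of mean signal. The percentile describes these libraries and is not a p-value; outside the central 95% it is called outside the matched range. Of 60 list medians over the 4 comparisons 6 were outside, and about 3 would be by chance. A gene counts as 2-fold changed by the mean over its regions.

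Named regions follow a rule. Per comparison they are the 8 highest and 8 lowest log2 ratios among regions with exactly 1 gene symbol in which the higher library reaches the median of that value, if at least 2-fold. For the difference between diets they are 5 in each direction, and for the level the 10 highest mean signals. Each list adds the 2 members with the highest mean signal and the most changed member on each diet. Predicted genes, Rik, microRNA and pseudogene names were skipped, which left out 9 regions. Some regions that meet the rule are not reported here. Genes named outside the rule are marked as picked after their values were seen, except in statements on list membership.

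The calculation was tested on simulated data for the comparison of TAC with sham on 10% fat diet. Of 50 regions with a true 2-fold rise 52.0% were found at least 2-fold higher, and of 50 with a 2-fold fall 48.0% at least 2-fold lower, since a true change at the threshold is missed about as often as found at any depth. Of 50 with a 4-fold rise and 50 with a 4-fold fall 88.0 and 98.0% were found. Of 3685 unchanged regions 3.12% were at least 2-fold higher and 3.20% lower, and 96.7% of the exact intervals held the true ratio. A list without change lay at percentile 32.6 and a list lowered 2-fold at percentile 0.

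The alternatives were pseudocounts of 0.1 and 10, a 1.5-fold threshold, the highest instead of the average signal, centring on the median, quantile normalization, filters on signal and calls, autosomes, a stricter call, single-gene regions, each gene's highest region and each distinct region of a list as 1 value, among random sets of regions. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.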

Results

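Binding of ACAA2 to heart chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq). ACAA2 is the mitochondrial 3-ketoacyl-CoA thiolase, an enzyme of fatty acid beta-oxidation. The hearts came from male C57BL/6J mice aged 12 weeks that ate a diet with 10 or 60 kcal% fat. After 4 days of diet the mice had sham surgery or transverse aortic constriction (TAC), which narrows the aorta and loads the left ventricle with pressure, and they stayed on their diet for 1 more week. The design crosses surgery with diet in 4 groups, with 1 library per group, each labelled a pool of 3 hearts. There were no replicates, so no spread between hearts is known and no comparison was tested. Intervals are at the 95% level. They cover counting error for the ratio of a region, the spread over regions for a median and sampling of genes or regions for a share, and none covers variation between hearts. The authors merged the called intervals of the 4 libraries into 3885 regions with a median length of 307 bp. Over these regions the sham library on 10% fat diet held an estimated 75313 fragments. The estimate was 68963 fragments for TAC on 10% fat diet, 49593 for sham on 60% fat diet and 62559 for TAC on 60% fat diet. The median region held 16.3, 14.9, 10.4 and 13.7 fragments in these libraries, in the same order, so the ratio of a single region is imprecise. The depth outside the regions and any scaling between the libraries are not given in the sources used here.

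ACAA2 signal lay mainly at gene starts. Of the 3885 regions, 82.6% held a promoter (Wilson interval 81.3 to 83.7%), 73.7% a CpG island (72.3 to 75.1%) and 69.8% both (68.3 to 71.2%). Only 6.10% had no gene assigned (5.39 to 6.90%), and the median distance from a region to the nearest assigned start site was 196.5 bp. In the 160 regions called in all 4 libraries the share with a promoter was 93.1% (88.1 to 96.1%) and the share with a CpG island 88.1% (82.2 to 92.3%). The libraries differed in how many regions carried a called interval, in the same order as in their estimated fragments over the regions. Their depth is not known, so these numbers cannot be read as a difference between hearts. The number was 2225 in sham hearts and 1820 in TAC hearts on 10% fat diet, against 600 in sham hearts and 1396 in TAC hearts on 60% fat diet. Most regions, 2479 or 63.8%, were called in 1 library, and 160 or 4.12% in all 4. The sham and TAC libraries shared 842 called regions on 10% fat diet and 259 on 60% fat diet. A region without a call was not without signal. The sham library on 60% fat diet had a median average signal (mean fragment pileup over a region) of 6.70 in the regions where it was not called and 11.9 where it was. Open promoters can give signal in any ChIP, and no input signal was set against these values.

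**Figure D1:**
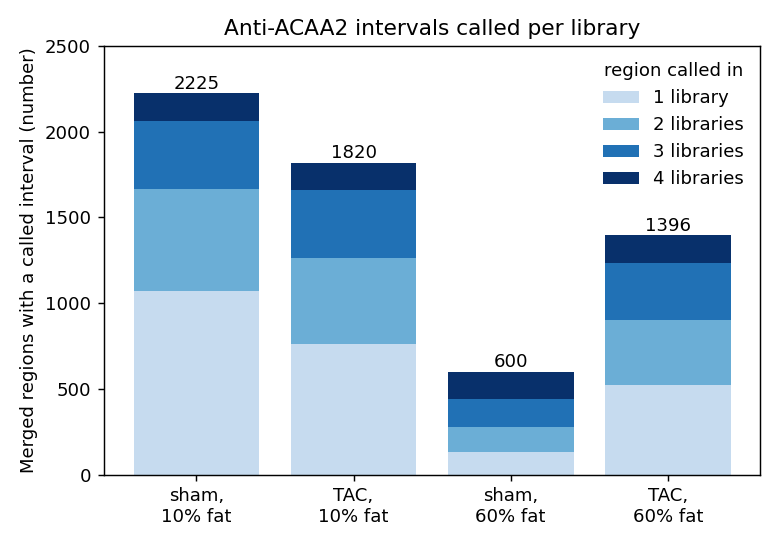
Bars show the number of merged regions with a called anti-ACAA2 interval in each library (1 library per group), with colours for the number of libraries in which a region was called. The bars reach 2225, 1820, 600 and 1396 regions, and 160 regions in each bar were called in all 4 libraries.

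Of the 10 single-gene regions named for the highest mean signal over the 4 libraries, 9 held a promoter. The first was upstream of Dgat2, which makes triglycerides (chromosome 7, 99182722 to 99183076 in mm10), with an average signal of 25.8 in sham and 13.9 in TAC hearts on 10% fat diet and of 16.8 and 22.5 on 60% fat diet. The others were at Sde2, Stat3, Tcf3, Ube2f, Lrpprc, Pim3, Hnrnph1, Cln6 and Utp3, and the one at Cln6 held no promoter. Stat3, a transcription factor of cytokine signalling, had a region at chromosome 11, 100939490 to 100939991, with signals of 20.1 and 24.7 in sham and TAC hearts on 10% fat diet and of 16.1 and 14.7 on 60% fat diet. Hnrnph1, a splicing factor, had 17.2, 18, 14.2 and 16.6 in the same order. The Acaa2 gene itself had 0 regions.

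Gene lists written before the data were examined differed in how many of their genes carried a region, against 20.8% of all 21896 protein-coding genes. The share was highest for immediate early and stress response genes, with 32 of 42 genes or 76.2% (Wilson interval 61.5 to 86.5%), among them Fos, Jun, Atf3 and Btg1. Circadian clock genes followed with 12 of 19 genes or 63.2% (41.0 to 80.9%), among them Arntl, Per1, Nr1d1 and Dbp. Genes of energy metabolism were also above the share of all genes. The TCA cycle and pyruvate dehydrogenase list had 17 of 31 genes or 54.8% (37.8 to 70.8%), including Ogdh and the pyruvate carrier Mpc1. Fatty acid uptake and beta-oxidation had 17 of 34 genes or 50% (34.1 to 65.9%), including the carnitine palmitoyltransferases Cpt1a, Cpt1b and Cpt2. Hadha and Hadhb, which encode the subunits of the mitochondrial trifunctional protein, shared 1 region at their common promoter. Glycolysis and glucose uptake had 12 of 25 genes (48%), oxidative phosphorylation 35 of 80 (43.8%) and metabolic transcription regulators 17 of 34 (50%). Ribosomal proteins had 49 of 85 genes (57.6%), RNA polymerase II and splicing 31 of 58 (53.4%), the proteasome 18 of 39 (46.2%) and histone genes 36 of 98 (36.7%), the last in only 20 regions because clustered histone genes share them. The intervals of these 11 lists lay above 20.8%. That background was not matched on CpG islands or expression, and it includes families with few regions, such as olfactory receptors (5 of 1106 genes). A higher share therefore does not single out a list as a target of ACAA2.

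Muscle genes and markers of other cell types did not stand above all genes. The sarcomere and Z-disc list had 9 of 40 genes (22.5%, interval 12.3 to 37.5%), 1 of which, Myh7, is also on the hypertrophy list. Calcium handling and ion channels had 7 of 28 (25%) and the hypertrophy and fetal gene program 11 of 34 (32.4%). Endothelial markers had 5 of 26 genes (19.2%), adipocyte markers 2 of 12 (16.7%), smooth muscle and pericyte markers 2 of 14 (14.3%), macrophage and leukocyte markers 3 of 26 (11.5%) and fibroblast and matrix markers 4 of 36 (11.1%). Skeletal muscle markers and neuron markers each had 2 of 19 genes (10.5%), and liver markers 1 of 19 (5.26%), the last through a region shared with the promoter of Tomm40l. Every one of these 11 intervals included 20.8%. The authors assigned 2 or more genes to 49.8% of regions. With only the regions assigned to 1 gene, 7 lists stood above all genes: sarcomere genes reached 2.31 times and hypertrophy genes 3.17 times the share of all genes. Histone genes turned to 0.157 times, and 5 further lists had intervals that included the share of all genes: oxidative phosphorylation at 0.577, ribosomal proteins at 0.904, glycolysis at 1.23, the proteasome at 1.97 and metabolic regulators at 2.26 times that share. With only the regions within 1000 bp of start sites, 10 lists stood above all genes. Hypertrophy genes, at 1.94 times, were then among them, and glycolysis (1.47) and histone genes (1.05) were not. Macrophage and leukocyte markers, with 0 such regions, fell below all genes.

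**Figure D2:**
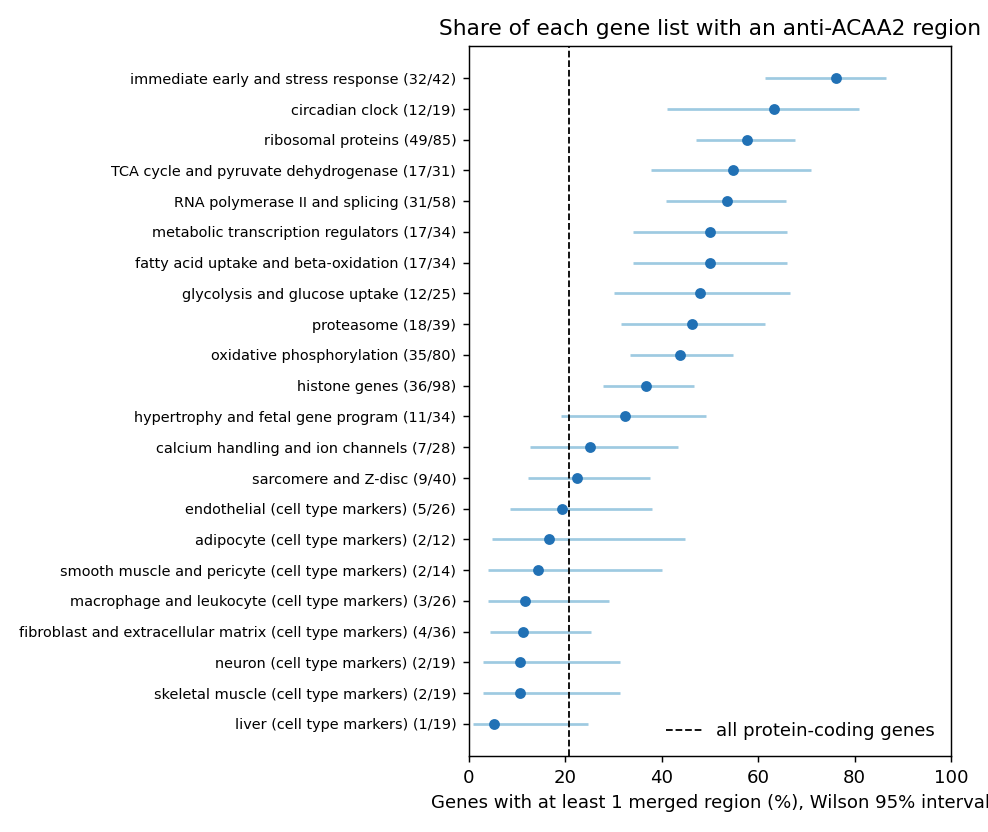
Points show the percent of genes in each list with at least 1 merged region, and lines the 95% Wilson interval. The dashed line marks the 20.8% of all protein-coding genes, above which the intervals of 11 of the 22 lists lie.

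The comparison of TAC with sham hearts on 10% fat diet asks how ACAA2 binding differs after pressure overload on the control diet. The median log2 ratio was -0.14 (-0.17 to -0.10) over all 3885 regions, and list values are given here relative to it. The 9 sarcomere and Z-disc genes had a median of -0.83, and 4 of them were at least 2-fold lower and 0 at least 2-fold higher. The 7 calcium handling genes also had a median of -0.83, with 2 genes 2-fold lower, the 36 histone genes -0.49, with 6 lower, and the 5 endothelial markers -1.01, with 3 lower. Among random gene sets matched on size and signal these medians lay at percentiles 0.525, 2.15, 0.05 and 1.06, below the matched range, but each lay within it under at least 1 alternative given below. The histone genes share 20 regions, and with each distinct region as 1 value that list lay at percentile 3.67.

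Named sarcomere regions pointed both ways, although only 1 of the 9 genes lay above the all-region median by the mean over its regions. Picked after their values were seen, Ttn, the titin gene, had a log2 ratio of -1.89 (counting interval -5.67 to -0.26) at a region inside the gene, Synpo2l -1.18 (-2.29 to -0.34) and Synpo2 -1.37 (-3.21 to -0.19). Xirp1 was at 1.20 (0.16 to 2.78) in 1 of its 2 regions and Pdlim5 at -0.63 (-1.87 to 0.29). Among calcium genes Cacna1c, the pore subunit of the cardiac L-type calcium channel and likewise picked afterwards, was at -1.87 (-4.19 to -0.57) and Calm2, a calmodulin gene, at -0.97 (-2.25 to 0.03). The vascular endothelial growth factor receptor gene Kdr was at -2.21 (-6.08 to -0.80) at chromosome 5, 75933645 to 75933875, inside the gene. Fatty acid oxidation genes had a relative median of -0.29, within the matched random range at percentile 10.0, with 4 of 17 genes 2-fold lower and 1 higher. Mlycd, malonyl-CoA decarboxylase, was at -1.10 (-2.31 to -0.28), and Acsl1, a long-chain acyl-CoA synthetase, at -1.04 (-3.01 to 0.50). Oxidative phosphorylation genes had a relative median of 0.046, within the matched range at percentile 56.8, and 18 of 35 genes lay above the all-region median. In that list 1 gene was 2-fold lower and 2 were higher. Ndufa4 was at -1.43 (-2.47 to -0.77) and 1 of 2 regions of Atp5g1 at -1.38 (-2.59 to -0.52). Other named members were higher. Rcan1, a feedback inhibitor of calcineurin, was at 1.5 (0.61 to 2.76), the clock repressor gene Cry1 at 1.09 (0.14 to 2.29) and the mesenchymal marker Vim at 1.27 (0.46 to 2.64). The TCA, glycolysis, hypertrophy, immediate early, metabolic regulator, clock, ribosomal, proteasome and RNA polymerase lists also stayed within the matched range. Alternatives put 4 of these lists below it. They were fatty acid oxidation (median log2 ratio -1.04, percentile 0.555) and hypertrophy genes (-0.78, percentile 1.88) in single-gene regions, the proteasome with each gene's highest region (-0.65, percentile 0.5) and the clock with each distinct region as 1 value (-0.44, percentile 0.765).

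Over all regions, 310 were at least 2-fold higher and 455 at least 2-fold lower after TAC on 10% fat diet. The highest log2 ratio by the naming rule was at Ep300, a histone acetyltransferase (chromosome 15, 81586373 to 81586616), with 2.55 (0.91 to 6.16), as the signal went from 1.67 to 14.6. Hexa, Wdr41, Hibadh, Plekhg5, Chd9, Slc44a2 and Lonrf1 followed, with 2.44 to 1.94. The lowest by that rule were Lrrc58 in 2 regions, Ank3, Tecr, Kdr, Fgfr1, Atp6v1g1 and Fndc3b, from -2.71 to -1.93. Tecr, the last enzyme of very-long-chain fatty acid elongation, had -2.60 (-6.46 to -1.28) at chromosome 8, 83594754 to 83595040. Fgfr1, a fibroblast growth factor receptor gene, had -2.12 (-4.75 to -0.50) at its promoter. Of the 2-fold regions 40.5% were higher, but 56.7% with ratios centred on the all-region median and 53.4% with quantile normalization. Both scalings draw this share towards balance by construction, here and in the comparisons below, so they do not show whether the imbalance is real. Binomial draws of the same fragments with no difference between libraries beyond their totals over the regions gave a mean of 77.6 regions 2-fold higher and 177 lower. The excess over the draws was smaller in the 1737 regions called in a library on 60% fat diet, where 55 were higher and 101 lower against 40.1 and 73.7 in the draws, and the median was -0.078 (-0.12 to -0.05). The sarcomere median left the extreme 2.5% with single-gene regions (percentile 8.81), each gene's highest region (2.53) or peak signal (3.09), the endothelial one with each gene's highest region (7.79), the histone one with regions within 1000 bp of start sites (3.15) and the calcium one without regions called in sham hearts on 60% fat diet alone (5.15) or with each distinct region as 1 value (8.07). In sham but not TAC hearts on 10% fat diet, 8 of the 9 sarcomere genes and 4 of the 7 calcium genes were called.

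**Figure D3:**
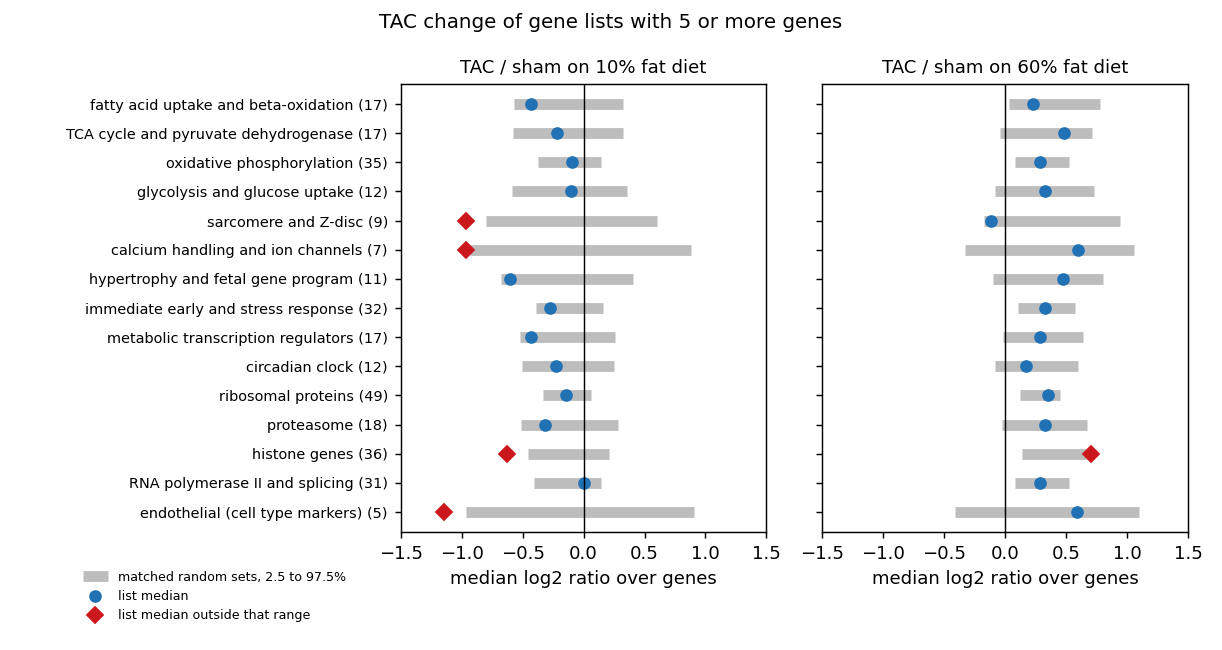
Points show the median log2 ratio of TAC over sham across the genes of each list with 5 or more genes, on 10% fat diet at left and 60% fat diet at right, and grey bars the central 95% range of 10000 random gene sets matched on size and signal. Red diamonds lie outside that range: 4 lists below it on 10% fat diet and histone genes above it on 60% fat diet.

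On 60% fat diet, the same comparison asks whether pressure overload goes with different binding in mice fed fat. Signal was higher after TAC over most regions, with a median log2 ratio of 0.32 (0.30 to 0.35), and 604 regions were at least 2-fold higher against 121 lower. Histone genes stood above the other lists, with a median of 0.38 relative to all regions at percentile 98.9 and 5 of 36 genes 2-fold higher, but not with peak signal (percentile 76.6), with regions within 1000 bp of start sites alone (79.6) or with each distinct region as 1 value (82.6). The sarcomere list had a relative median of -0.44 at percentile 3.77, within the matched range, with 0 of 9 genes 2-fold changed. It lay below that range with each gene's highest region (percentile 1.76), with each distinct region as 1 value (1.19) and without regions called in sham hearts on 60% fat diet alone (2.2). The other 13 lists with a median lay within it too. Of 17 fatty acid oxidation genes 4 were 2-fold higher and 2 lower, among them Acsl1 with 1.81 (0.38 to 4.66) and Mlycd with -1.38 (-3.28 to -0.28). Of 32 immediate early and stress genes 3 were 2-fold higher and 0 lower, including the heat shock gene Dnajb1, with 2.08 (0.56 to 5.89) in 1 of its 2 regions. The stress transcription factor gene Atf3 was not 2-fold changed by the mean of its 2 regions, of which the one at the promoter had 1.5 (0.37 to 3.12). Of 49 ribosomal protein genes 8 were 2-fold higher and 0 lower, with Rps7 at 1.03 (0.08 to 2.24). Acly, which makes cytosolic acetyl-CoA from citrate, was at 1.74 (0.14 to 3.87), 1 of 2 regions of Foxo3 at 0.91 (0.08 to 2.08) and 1 of 3 regions of the H2A variant gene H2afv at 1.39 (0.21 to 3.00).

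The highest ratio on 60% fat diet by the naming rule was at Degs1, an enzyme of ceramide synthesis (chromosome 1, 182282628 to 182282873), with 2.73 (1.11 to 6.32), from a signal of 1.57 in sham to 16.0 in TAC hearts. Ern1, the IRE1 sensor of the unfolded protein response (chromosome 11, 106487885 to 106488094), had 2.45 (1.11 to 6.32). Cap1, Endod1, Rgs3, Fam102b and Hint3 followed, with 2.44 to 2.21. The lowest by that rule were Ddx3y, Ccdc171, Nudt7, Wisp3, Sptssa, Lars2, Txlnb and Ruvbl1, from -2.40 to -1.44. Sptssa, a small subunit of serine palmitoyltransferase in sphingolipid synthesis, was at -1.68 (-3.83 to -0.62), and Lars2, the mitochondrial leucyl-tRNA synthetase, at -1.56 (-4.36 to 0.05). Of the 2-fold regions 83.3% were higher, but 47.6% after centring and 49.4% after quantile normalization, again by construction. The draws gave 403 higher and 65.6 lower. In the 3203 regions called in a library on 10% fat diet, the median was 0.26 (0.23 to 0.28), with 318 higher and 69 lower against 286 and 66.4 in the draws.

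**Figure D4:**
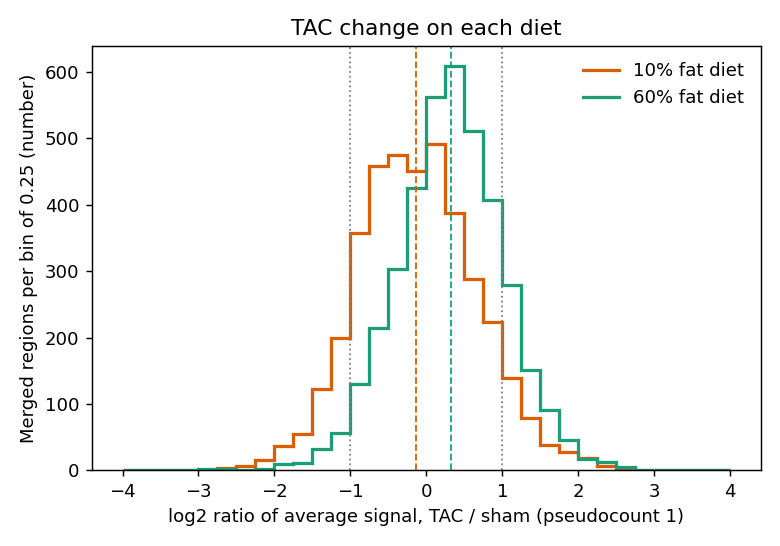
Lines show the number of merged regions per bin of 0.25 of the log2 ratio of TAC over sham average signal, for each diet, over 3885 regions. Dashed lines mark the medians of -0.14 on 10% and 0.32 on 60% fat diet, and dotted lines the 2-fold bounds.

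In sham hearts, the comparison of 60% with 10% fat diet addresses diet without pressure overload. Signal was lower on 60% fat diet across most regions, with a median log2 ratio of -0.57 (-0.60 to -0.54), and 962 regions were at least 2-fold lower against 78 higher. The median was -0.55 (-0.58 to -0.51) in promoters with a CpG island and -0.67 (-0.76 to -0.55) in gene windows without a promoter. Endothelial markers lay furthest below the other genes, with a median of -0.94 relative to all regions at percentile 1.05 and 3 of 5 genes 2-fold lower, but at percentile 23.2 with each gene's highest region. This ratio and the TAC ratio on 10% fat diet share the sham library on 10% fat diet. High signal at these genes in that library alone would lower both, so the endothelial results are not independent. The other 14 lists lay within the matched range. Without regions called in sham hearts on 60% fat diet alone, fatty acid oxidation genes lay below it (median -0.99, percentile 2.15). In fatty acid oxidation 7 of 17 genes were 2-fold lower and 0 higher, in oxidative phosphorylation 8 of 35 lower and 2 higher and among ribosomal proteins 15 of 49 lower and 0 higher, with relative medians of -0.08, -0.01 and -0.05.

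Single-gene regions far lower on 60% fat diet in sham hearts were at Ank3, Fam154a, Spty2d1, Slc25a4, Fndc3b, Cdc14a and Dcaf10, from -2.86 to -2.42. Slc25a4 encodes the ADP/ATP translocase of heart mitochondria, and its region (chromosome 8, 46208375 to 46208605) had -2.57 (-6.16 to -0.91). The regions furthest higher by the naming rule were at Cebpg, Ncoa7, Commd9, Itpr1, Ccdc171, Camk2g, Dcaf8 and Lipt2, from 2.36 to 1.13. Cebpg, a transcription factor gene of the amino acid response, had 2.36 (0.42 to 5.79), and Itpr1, an intracellular calcium release channel gene, 1.26 (-0.20 to 3.22). Outside the rule, the phospholamban gene Pln had a region also assigned to Cep85l at 2.60 (0.51 to 8.76). Of the 2-fold regions 7.50% were higher, but 54.7% after centring and 51.3% after quantile normalization. The draws gave 24.0 higher and 738 lower. In the 2615 regions called in a TAC library the median was -0.42 (-0.44 to -0.39), with 32 higher and 371 lower against 27.2 and 379 in the draws.

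In TAC hearts, the same diet comparison addresses diet under pressure overload. The median shift was smaller than in sham hearts, with a log2 ratio of -0.14 (-0.17 to -0.12), and 272 regions were at least 2-fold higher and 440 lower on 60% fat diet. Apart from that shift the libraries were not closer. After centring, 368 regions were 2-fold higher and 307 lower, against 321 and 266 in sham hearts. None of the 15 lists with a median lay outside the matched range, but 3 did under alternatives: ribosomal proteins in single-gene regions (median -0.85, percentile 1.17), and hypertrophy genes (0.42, percentile 97.9) and RNA polymerase II and splicing genes (-0.42, percentile 2.24) with regions within 1000 bp of start sites. Calcium handling genes had the highest relative median, 0.59 at percentile 92.5, and RNA polymerase II and splicing genes -0.15 at percentile 9.60, with 3 of 31 genes 2-fold lower and 0 higher. Of 36 histone genes, which share 20 regions, 5 were 2-fold higher and 0 lower. Named members that were lower were Xirp1 with -1.66 (-3.41 to -0.45) in a single region of the gene and Vim with -1.07 (-2.31 to -0.28). The proteasome ATPase genes Psmc1 with -1.39 (-2.51 to -0.61) and Psmc4 with -1.12 (-2.16 to -0.27) were lower too.

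Single-gene regions far higher on 60% fat diet in TAC hearts were at Nrp1, Fam43a, Zdhhc7, Ssh1, Msi2, Pde4b and Tns1, from 2.13 to 1.84. Nrp1, a coreceptor gene for vascular growth factors, had 2.13 (0.50 to 4.75), and the cAMP phosphodiesterase gene Pde4b 1.88 (0.11 to 4.47). The furthest lower by the naming rule were at F12, Mef2a, Gab1, Dcaf8, Plekhg5, Trdmt1, Atf7ip and Tjp1. The F12 region (chromosome 13, 55429294 to 55429499) had a signal of 13.3 on 10% fat diet and is listed at 0 on 60% fat diet, 4.07-fold lower against a floor of 3 fragments in that library. The counting interval, which also covers the error of the count on 10% fat diet, puts the log2 ratio at -1.47 or lower. Mef2a, a muscle transcription factor gene, had -2.64 (-8.89 to -0.68) in a region inside the gene but -0.37 (-1.16 to 0.35) at its promoter. Tjp1, a tight junction gene, had -2.19 (-5.79 to -0.42). Of the 2-fold regions 38.2% were higher, but 54.5% after centring and 51.8% after quantile normalization. The draws gave 85.6 higher and 202 lower. In the 2464 regions called in a sham library, 80 were higher and 128 lower against 59.6 and 117 in the draws, with a median of -0.11 (-0.13 to -0.08).

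The difference between diets in the TAC change compares the log2 ratios of TAC over sham on 60% and 10% fat diet. Its median was 0.45 (0.41 to 0.49), with 1123 regions at least 1 log2 unit higher on 60% fat diet and 338 lower. Endothelial markers had a median difference of 1.31 relative to all regions at percentile 98.9, which fell to percentile 68.1 with each gene's highest region, 96.9 with peak signal and 92.1 with each distinct region as 1 value. Histone genes had a relative median of 0.41 at percentile 96.4. Their percentile was 98.8 with peak signal and 99.9 without regions called in sham hearts on 60% fat diet alone. Of 36 histone genes 17 were above 1 log2 unit and 0 below -1. These genes share 20 regions, so the count repeats regions and random gene sets are too narrow for the list. Fatty acid oxidation genes had a relative median of -0.24 at percentile 13.7. The sham library on 10% fat diet enters the difference too, so the endothelial value here is not independent of the endothelial results above. By the naming rule the largest positive differences were at Fndc3b, Dcaf10, Ern1, Fgfr1 and Tecr. Fndc3b, a gene of adipocyte differentiation (chromosome 3, 27631255 to 27631580), had signals of 18.4 in sham and 4.10 in TAC hearts on 10% fat diet and of 2.5 and 12.6 on 60% fat diet, a difference of 3.89. The most negative were at Plekhg5, Ccdc171, Nfia, Tmem38b and Gtf2a1. Tmem38b, which encodes a channel of the sarcoplasmic and endoplasmic reticulum, had log2 ratios of 1.76 (0.95 to 3.41) on 10% and -0.57 (-2.05 to 0.44) on 60% fat diet. Of the regions past 1 log2 unit 76.9% were higher, but 48.1% after centring and 49.7% after quantile normalization. The 310 regions that were 2-fold higher after TAC on 10% fat diet had a median of 0.32 on 60% fat diet (0.25 to 0.41) and the 455 that were lower 0.29 (0.21 to 0.36), close to the 0.32 of all regions. Of the 310 regions 53 were 2-fold higher on both diets, against 48.2 for independent lists, and of the 455 lower regions 26 were lower on both, against 14.2. Independent lists assume that every region passes 2-fold equally often. Regions with few fragments can pass more readily on both diets, so these counts do not show a shared change.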

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

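In this part the tests on regions called in libraries not compared, the one on the fragments of the sham library on 60% fat diet and those on distinct regions were chosen only after the results were seen. The results below drew attention because TAC and sham hearts differed in opposite directions on the 2 diets. None of these differences was tested, because each group has 1 library. Each value is the log2 ratio of TAC over sham on 60% fat diet minus that on 10% fat diet.

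Over all 3885 regions the difference was 0.45, with medians of -0.14 on 10% and 0.32 on 60% fat diet. Of the 15 lists with a median, 13 had opposite signs. A shift of all regions alike gives such signs by itself. Relative to the medians of all regions, 9 of the 13 had opposite signs, several of them near 0, and 4 had the same sign on both diets: fatty acid oxidation (-0.29 and -0.094), metabolic regulators (-0.29 and -0.042), the clock (-0.086 and -0.15) and glycolysis (0.035 and 0.0046). The differences were 0.21 for fatty acid uptake and beta-oxidation, 0.51 for the TCA cycle, 0.50 for oxidative phosphorylation, 0.54 for glycolysis and 0.48 for metabolic transcription regulators. They were 1.05 for calcium handling, 0.90 for the hypertrophy program, 0.52 for immediate early and stress genes, 0.35 for the clock, 0.54 for ribosomal proteins and 0.71 for the proteasome. Histone genes had 0.87 and endothelial markers 1.77. Relative to the median of all regions, the endothelial list lay above the matched random range at percentile 98.9, but not with peak signal (96.9), each gene's highest region (68.1) or each distinct region as 1 value (92.1). Histone genes lay above it only with peak signal (98.8) or without regions called in sham hearts on 60% fat diet alone (99.9). The 36 histone genes share 20 regions, so random gene sets are too narrow for these percentiles. The 10 regions named for the difference also had opposite signs: Fndc3b with 3.89, Dcaf10 with 3.61, Ern1 with 3.15, Fgfr1 with 3.12 and Tecr with 2.96 on the positive side. On the negative side they were Plekhg5 with -2.93, Ccdc171 with -2.71, Nfia with -2.50, Tmem38b with -2.33 and Gtf2a1 with -2.30. They were picked as extremes of the differences among the single-gene regions that pass the signal filter of the naming rule.

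The opposite signs over all regions are the first pattern weighed. Selection of regions by calls in the compared libraries cannot be the whole cause, since regions called in libraries of the other diet still had medians of -0.078 (-0.12 to -0.05) on 10% and 0.26 (0.23 to 0.28) on 60% fat diet. A lower depth or enrichment of the sham library on 60% fat diet, which would raise the TAC ratio there, cannot be told apart from an effect of surgery. The log2 ratio of fragments over all regions is 0.34, and no depth from outside the regions is known to divide by. The same holds for the lower signal on 10% fat diet. There the TAC library held an estimated 68963 fragments over the regions, against 75313 in the sham library. An effect of diet on the response to pressure overload stays open and untested.

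The lower signal in sham hearts on 60% than on 10% fat diet is the next pattern. Selection by calls in the sham library on 10% fat diet cannot be the whole cause, because regions called in a TAC library had a median of -0.42 (-0.44 to -0.39). A single factor for the whole library, such as depth, predicts the same ratio in weak and strong regions. In regions called in a TAC library, grouped in tertiles by TAC signal, each tertile had a log2 ratio of -0.46, and the highest and lowest differed by -0.000411 (-0.06 to 0.06), in line with one factor. Fewer enriched fragments at all regions alike, of technical or dietary origin, would give the same picture, so the diet stays open too.

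The lists that were lower after TAC on 10% fat diet are the last pattern. A region called in sham but not in TAC hearts tends to be lower after TAC, so random gene sets matched on calls in the compared libraries are lower too. These sets were matched on calls instead of signal. A list below such sets argues against selection by calls as the whole cause, while a list among them decides nothing. The endothelial median lay below such sets at percentile 0.88, but the 6 regions taken singly lay among them at 4.22. With only 5 genes the calls stay undecided for this list. The sarcomere list lay at 4.13 and the calcium list at 2.73. On 10% fat diet 8 of 9 sarcomere genes and 4 of 7 calcium genes were called in sham but not in TAC hearts, against 32.3% of all genes with a region. Regions called on 60% fat diet, whose calls do not depend on the compared libraries, were few. The 5 such calcium regions had a median of -0.022 at percentile 56.7, so the lower signal was not present there, as selection by calls would predict. Only 2 sarcomere genes had such a region. With so few regions, selection by calls cannot be told apart from an effect of TAC for both lists.

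The histone list lay at 0.33, but its 36 genes rest on 20 regions, so random sets of 36 genes are too narrow for it and that value excludes nothing. The distinct histone regions lay at 5.49 when matched on calls. The 7 called on 60% fat diet had a median of -0.54 at percentile 2.17 when matched on signal, so the lower signal was also present there. With so few regions the calls cannot be told apart from an effect of TAC for this list either. Matching on a promoter region with a CpG island, instead of signal, left the sarcomere list at 0.32, calcium at 0.45 and endothelial at 0.84. This argues against the lack of such a region as the whole cause, although single calcium regions lay at 4.48. Where a region lies inside a gene was not matched, so position in that sense stays open. For histone genes the same matching gave 0.02, and 2.58 for distinct regions, so the lack of such a region stays undecided as a cause there. Pressure overload stays open as an untested explanation for all 4 lists.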

How the results depend on the processing

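The regions called in a library not compared, the authors' log2 ratios, the regions near start sites, the regions called outside the sham library on 60% fat diet, quantile normalization of the lists and distinct regions as the unit of a list were chosen after seeing the data. Values below are for the 5 results in order: TAC on 10% fat diet, TAC on 60% fat diet, diet in sham hearts, diet in TAC hearts and the difference between diets. Apart from scaling, which brings the medians near 0, every median kept its sign in every alternative. The cause was not tested unless named.

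Fold counts follow the pseudocount by construction. With a pseudocount of 10 the medians were -0.077, 0.16, -0.30, -0.077 and 0.25, with 8, 14, 1, 3 and 200 regions higher and 11, 4, 40, 10 and 33 lower. With 0.1 the medians were 0.36, -0.63 and 0.49 for TAC on 60% fat diet, diet in sham hearts and the difference, and 187 regions were lower after TAC on 60% fat diet. In the authors' log2 ratios, with no pseudocount, TAC on 60% fat diet had a median of 0.37 with 192 regions lower, and diet in sham hearts -0.64. A 1.5-fold threshold counts more regions by construction: 709, 1339, 214, 639 and 1734 higher and 1110, 379, 1920, 1051 and 622 lower.

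Centring sets the medians to 0 by construction. It gave 272 higher and 300 lower regions for TAC on 60% fat diet, 321 and 266 for diet in sham hearts and 601 and 649 for the difference. Quantile normalization gave medians of -0.0262, 0.00235, -0.0148, -0.0147 and 0.0284. Its counts were 275 and 282 for TAC on 60% fat diet, 290 and 275 for diet in sham hearts and 618 and 625 for the difference. Peak signal gave medians of 0.29, -0.49, -0.12 and 0.37 for all but TAC on 10% fat diet, which stayed within its interval.

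Filters changed the regions counted. In regions whose highest library reached the median, TAC on 10% fat diet had a median of -0.23, with 164 higher and 243 lower, and TAC on 60% fat diet 0.50, with 68 lower. Diet in sham hearts had -0.78 with 36 higher, diet in TAC hearts -0.30 with 161 higher and 293 lower, and the difference 573 higher and 152 lower. In regions called in a compared library the medians were -0.17, 0.55, -0.75 and -0.23, with 67 lower for TAC on 60% fat diet. In regions called in a library not compared they were -0.078, 0.26, -0.42 and -0.11, with 55, 318, 32 and 80 higher and 101, 69, 371 and 128 lower. Autosomes alone changed none of these beyond their bounds.

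A stricter call, at or above the median signal of called regions, left 1290 regions for sham and 959 for TAC on 10% fat diet and 166 and 609 on 60% fat diet, fewer by construction. In regions called in all 4 libraries 93.1% held a promoter, 88.1% a CpG island and 2.5% had no gene. With single-gene regions, 7 instead of 11 lists had a share above all genes, and the histone share turned from above to 0.157 times that of all genes, which follows from the shared regions of clustered histone genes. With regions near start sites 10 lists did: hypertrophy genes joined at 1.94, glycolysis (1.47) and histone genes (1.05) were lost, and macrophage and leukocyte markers fell below all genes at 0. Of the list medians, 3 of 40 lay outside the matched range with single-gene regions and 2 of 48 with regions near start sites, and none of these was among the 6 of 60 reported. With each distinct region as 1 value 5 of 60 lay outside, of which 3 were among the 6. Centring cannot change a percentile by construction, and under quantile normalization the 6 remained outside on the same side. Of the 74 regions named as higher or lower, 37 stayed 2-fold with a pseudocount of 10, 71 with peak signal and 74 with quantile normalization, and 0 changed direction with peak signal or quantile normalization. Centring and a pseudocount of 0.1 kept all 74, which shows little: the regions are extremes, centring moves them by less than their margin, and a smaller pseudocount enlarges a ratio.

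For the comparisons made here, no paired analysis was possible because each sets 1 library against 1, so no replicate could be left out or used as a block. A surgery effect common to both diets, with sham and TAC paired by diet, would rest on 2 pairs and was not estimated. The input was not subtracted, and called intervals per library were not counted, since the table gives their total alone: 6109, against 6041 called regions summed over the libraries.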

Other observations

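The gene families, genes and positions in this part were picked after their values were seen. Housekeeping families beyond the lists also carried ACAA2 regions more often than the 20.8% of all protein-coding genes. Mitochondrial ribosomal proteins had 36 of 78 genes or 46.2% (Wilson interval 35.5 to 57.1%), DEAD and DEAH box helicases 27 of 53 or 50.9% (37.9 to 63.9%) and aminoacyl-tRNA synthetases 16 of 34 or 47.1% (31.5 to 63.3%). Translation initiation factors had 22 of 56 genes or 39.3% (27.6 to 52.4%), ubiquitin-conjugating enzymes 14 of 37 or 37.8% (24.1 to 53.9%) and Rab GTPases 22 of 59 or 37.3% (26.1 to 50.05%). Zinc finger genes, with 85 of 367 or 23.2% (19.1 to 27.7%), and solute carriers, with 57 of 337 or 16.9% (13.3 to 21.3%), had intervals that included 20.8%. The same held for collagens, with 5 of 44 genes or 11.4% (4.95 to 24.0%). Other families carried regions less often than all genes: 5 of 1106 olfactory receptor genes or 0.452% (0.193 to 1.05%), 5 of 92 cytochrome P450 genes or 5.43% (2.34 to 12.1%), 1 of 49 keratin genes (up to 10.7%), 1 of 37 interleukin genes (up to 13.8%), 0 of 353 vomeronasal receptor genes (up to 1.08%) and 0 of 39 Hox genes (up to 8.97%).

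Several genes carried a row of separate regions. Nfia, a transcription factor gene, had 8 regions between 97751101 and 97869533 on chromosome 4, of which 5 were called in sham hearts on 10% fat diet alone and 0 lay at a promoter. Cd36, the fatty acid transporter of the heart, had 5 regions between 17812513 and 17886485 on chromosome 5, of which 4 were called in that library alone. Their mean signal was 10.0 in sham and 3.66 in TAC hearts on 10% fat diet and 3.75 and 6.94 on 60% fat diet. The log2 ratios of TAC over sham on 10% fat diet at these regions ran from -2.43 (-9 to -0.83) to 0.31 (-1.71 to 2.31). Bcl2l1, Hnrnpl, Pim3, Ptma, Sgk1, Trappc9, Wee1 and Zbtb16 had 4 each. Zbtb16, a transcription factor gene, was called in all 4 of its regions in sham hearts on 10% fat diet, with mean signals of 18.1 there and 12.0, 9.76 and 10.1 in the other libraries.

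Regions inside a single gene and over 1000 bp from its start were more frequent among regions called in 1 library. They made up 12.0% (10.2 to 14.1%) of the 1068 regions called in sham hearts on 10% fat diet alone, 8.55% (6.77 to 10.8%) of the 760 in TAC hearts on 10% fat diet alone and 9.4% (7.19 to 12.2%) of the 521 in TAC hearts on 60% fat diet alone. In the 130 regions called in sham hearts on 60% fat diet alone the share was 9.23% (5.36 to 15.4%). In the 1406 regions called in more than 1 library it was 3.41% (2.58 to 4.50%). After TAC on 10% fat diet the 440 regions in gene windows without a promoter had a median log2 ratio of -0.33 (-0.42 to -0.18), against -0.09 (-0.14 to -0.06) in the 2711 at promoters with a CpG island. Of the 440 regions, 157 were called in sham hearts on 10% fat diet alone and 95 in TAC hearts on that diet alone. Of the 2711 regions these numbers were 663 and 511. Regions called in sham hearts alone tend to be lower after TAC, so selection by calls cannot be told apart from position here.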
